A study of Cardamine amara and Cardamine flexuosa and Cardamine hirsuta with 27 samples.

How the data were processed

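Transcript levels were measured in seedlings of the bittercress species Cardamine amara, C. hirsuta and C. flexuosa on 27 one-colour Agilent arrays whose probes were designed for Arabidopsis thaliana. Each species had 3 groups of 3 arrays: untreated controls taken at 0 h, seedlings severed at the hypocotyl and left to dry for 2 h (dry), and whole potted seedlings submerged in bubbled water for 2 h (wet). Per the labels, plants grew under 16 h light and 8 h dark at 22 and 20 °C and 60% humidity, and 0.6 ug RNA from the above-ground parts went into each labelling. Controls were taken 2 h before the treated plants, so time of day differed in every comparison with a control and in none of dry against wet. The labels do not say that plants or pools of replicates were separate, so p-values measure the spread between these samples.

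The deposited scanner files came from Agilent Feature Extraction 10.5.1.1. Per their headers the processed signal is a linear intensity with background subtracted and spatial trends removed. The multiplicative detrend was skipped only on C. hirsuta control replicate 1 and wet replicate 2. Deposited median spot and background signals are also intensities, and deposited flag columns hold yes or no marks per spot. The authors' deposited value table holds the median spot signal within rounding, a linear intensity neither background-subtracted nor normalized between arrays. The medians of its columns for replicates 1, 2 and 3 were 48.0, 50.5 and 49.0 in C. amara control, 47.0, 53.0 and 39.0 in dry and 51.0, 45.0 and 39.0 in wet. In C. hirsuta they were 44.5, 37.0 and 48.0 in control, 43.5, 41.0 and 36.0 in dry and 47.0, 43.0 and 45.0 in wet. In C. flexuosa they were 54.0, 50.0 and 49.5 in control, 46.0, 43.5 and 49.0 in dry and 48.0, 46.0 and 47.0 in wet.

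For 25 arrays the scanner file held the values of its own column of the value table, with at least 99.89% of probes equal within 0.1%. The scanner files attached to C. flexuosa control replicate 1 and C. hirsuta control replicate 1 held each other's columns, with 99.89% of probes equal to the other's column and 2.7% to their own. Those 2 arrays were assigned by the value table, and the assignment as attached was run as an alternative.

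Each array carried 45220 spots, of which 1417 were control spots and 43603 were probes, 88.1% with an Arabidopsis locus. After 478 probes with an outlier mark on any array were left out, 43125 probes remained for 28795 loci. Of these loci, 7197 had several probes and took the probe with the highest mean signal. Another 5133 kept probes had no locus and were tested apart. Symbols were given only to the 412 loci of 20 gene lists, since scanner files give loci and no gene table was used. The array genome is Arabidopsis, so no Cardamine coordinates are given.

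The log2 processed signal minus the log2 of its 75th percentile on the same array was fitted with limma 3.58.1 in R 4.3.3, with 9 groups, 18 residual degrees of freedom and a mean-variance trend. A gene was tested in a species if its probe was well above background, by the scanner's mark, on all arrays of at least 1 of the 3 groups. Differences between species in a response were tested as interactions on genes tested in both. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 and its change at least 2-fold, which is 1 on the log2 scale. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, both adjusted over all lists and comparisons. Where a gene was not well above background on any array of a group, its change is given as a lower bound, with each level of that group raised to at least the lowest signal that was well above background on the same array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

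The gene lists and the rule for naming genes were fixed before the data were examined. In each treatment against control the rule took the 6 largest rises and the 6 largest falls among called listed genes with all 3 treated arrays beyond all 3 controls and all well above background. It added 3 members of each main list, which were ABA and dehydration, jasmonate and wounding, early stress and touch regulators and heat shock for dry, and hypoxia core, ethylene, carbon starvation and auxin and growth for wet. The remaining lists gave their largest called member each. In dry against wet and in each interaction it took the 4 largest changes in either direction. The remaining lists were photosynthesis, circadian clock, aquaporins, cytosolic ribosome, flavonoid, glucosinolate, salicylate defence, cell cycle, root markers, stomatal lineage and guard cell markers, meristem and floral markers, and reference genes. Genes named outside the rule are marked as such.

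The arrays were scanned on 2 dates, with 15 on the first and 12 on the second. In each species 1 control and 2 arrays of each treatment fell on the first date, and the other 2 controls with 1 array of each treatment on the second. Fits with scan date as a block, over all arrays or within species, and fits to the arrays of each date alone stand beside the results. A group with a single array on a date was assumed to vary like the other groups. The deviations of same-number dry and wet arrays from their group means correlated at 0.133 to 0.633 in all 9 pairs. These pairs also shared a scan date, and in C. flexuosa a slide, so a pairing by number cannot be told apart from date or slide. The labels do not say what a number shares. The replicate block is given beside dry against wet where it changed a call. Other alternatives were quantile normalization, a 75th percentile over probes well above background on all arrays, normexp background correction with an offset of 50, and the value table in place of the processed signal. No filter or a stricter filter on dim probes, the mean of all probes of a gene, limma without the trend, no fold minimum, only arrays of the species compared, a slide block, a replicate block, and leaving out each array were also run. Normexp used the median spot signal, as the mean was not given. That form of it, the fits by date, the scan block for gene lists, the scan block within species, the scanner files as attached, the fit without the exchanged arrays and the test of early stress regulators with replicate 1 as the only C. amara control were chosen after the data were seen. The pipeline was tested on simulated data with each gene's mean and residual spread from these arrays. The simulated noise was independent between genes and arrays and held no effect of scan date, so its false calls are no error rate for these arrays. With 100 genes spiked per size, it recovered 38% of changes of 1.5 on the log2 scale and 90% of changes of 3 in dry against control in C. amara, with 6 false calls among 15941 genes. For the wet response in C. flexuosa minus C. amara it recovered 12% and 72%, with 5 false calls among 15242 genes. No probe sequences or Cardamine genomes were used here, so probe mismatch was not computed.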

Results

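Arrays of C. amara, C. hirsuta and C. flexuosa, an allotetraploid whose parents were the other species, were compared after drying or submergence for 2 h. Each of the 9 groups had n = 3 arrays. On single arrays 44.9 to 63.9% of probes were well above background, lowest in C. hirsuta control replicate 2 and highest in C. flexuosa control replicate 1, and 0 spots were saturated. Arrays of a group correlated with each other at 0.919 to 0.985, lowest on average in C. amara control at 0.943 and highest in C. flexuosa dry at 0.982. Assigned by the value table, C. flexuosa control replicate 1 correlated at 0.937 with the other C. flexuosa arrays and at 0.831 with C. hirsuta. As attached, its scanner file correlated at 0.846 with C. flexuosa and at 0.944 with C. hirsuta. The number of arrays limits the precision of every value. Because probes were designed for another genus, a difference in signal between species is not read as a difference in expression.

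Changes are log2 values ± SE from limma, and the values in parentheses after a change, or after a list's median, are those within the first and the second scan date. The only first-date control of C. hirsuta and of C. flexuosa was control replicate 1, an exchanged array. First-date values against control in these species, and first-date differences between species, therefore rest on the assignment of those arrays. Each gene with a symbol that is called against control below had its 3 treated arrays beyond all 3 controls. The rule named 239 gene results, of which 235 were still called with scan date as a block, with values that moved by at most 0.41. Treated arrays beyond all controls fix the sign of a change on both dates, so that agreement of signs is no evidence for a named gene. Over all genes tested, the changes of the first and the second date correlated at 0.382, 0.806 and 0.760 in dry and at 0.284, 0.535 and 0.330 in wet C. amara, C. hirsuta and C. flexuosa, and at 0.733, 0.862 and 0.867 in dry against wet. For the differences C. amara minus C. hirsuta, C. flexuosa minus C. amara and C. flexuosa minus C. hirsuta they correlated at 0.294, 0.218 and 0.484 in dry and at 0.307, 0.106 and 0.114 in wet. Whether more genes rose or fell changed side under at least 1 alternative in all 15 comparisons, so neither direction is taken to prevail.

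The dry comparison asked which transcripts changed in severed, drying seedlings. Controls were untreated, so effects of cutting and water loss cannot be told apart. In C. amara, genes of abscisic acid (ABA), the hormone that plants make under water loss, rose together. NCED3 (AT3G14440), the rate-limiting enzyme of ABA synthesis, rose by 5.78 ± 0.48 (6.94, 5.29; adjusted p = 1.43e-09). HB-12 (AT3G61890), an ABA-responsive homeodomain gene, rose by 8.00 ± 0.30 (8.45, 7.76; adjusted p = 1.74e-15). The NAC transcription factor RD26 (AT4G27410) rose by 6.39 ± 0.45 (7.46, 5.69) and GOLS2 (AT1G56600), which makes the osmoprotectant galactinol, by 6.76 ± 0.42 (6.23, 7.16). Of 27 tested ABA and dehydration genes 23 rose and 4 were not called, with 24 up when adjusted over the list alone. Their median was 3.55 (3.77, 3.97) with camera adjusted p = 8.67e-23.

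Jasmonate and wounding genes also rose in dry C. amara, with 15 of 23 up, 15 adjusted over the list alone, and a median of 1.57 (1.67, 1.88; adjusted p = 6.96e-07). Among them JMT (AT1G19640), which methylates jasmonate, rose by 4.51 ± 0.48 (4.81, 4.48), and LOX3 (AT1G17420), a lipoxygenase of jasmonate synthesis, by 7.30 ± 0.55 (5.69, 8.41) from controls of which 2 of 3 were well above background. Carbon starvation genes rose in 12 of 20 cases, 13 adjusted over the list alone, with a median of 1.76 (1.62, 1.65; adjusted p = 4.25e-06). Aquaporins, the water channels, rose in 11 of 15 cases and fell in 1, with the same counts adjusted over the list alone and a median of 1.99 (2.42, 1.87; adjusted p = 2.27e-08, but adjusted p = 0.0599 with an estimated correlation). PIP2;1 (AT3G53420), a plasma membrane aquaporin, rose by 5.24 ± 0.29 (5.25, 5.32). Flavonoid genes rose in 6 of 12 cases, 7 adjusted over the list alone, with a median of 1.28 (1.1, 1.29; adjusted p = 0.00179, but adjusted p = 0.143 with an estimated correlation), among them the anthocyanin regulator PAP2 (AT1G66390) at 4.64 ± 0.45 (4.87, 4.43), with 2 of 3 controls well above background.

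Of 23 auxin and growth genes in dry C. amara 10 fell and 3 rose, with 11 down and 4 up adjusted over the list alone and a median of -0.93 (-0.53, -1.18; adjusted p = 0.000884, but adjusted p = 0.123 with an estimated correlation). The expansin EXPA1 (AT1G69530), which loosens cell walls, fell by 3.5 ± 0.50 (-4.53, -3.63), and PRE1 (AT5G39860), a growth-promoting bHLH factor, by 4.13 ± 0.47 (-3.38, -4.38). PRE5 (AT3G28857) was at least 40.3-fold lower, as no dry array was well above background. Photosynthesis genes fell in 10 of 39 cases, 10 adjusted over the list alone, with a median of -0.68 (-0.50, -0.64; adjusted p = 8.58e-05, but adjusted p = 0.59 with an estimated correlation), for example the light-harvesting gene LHCB4.2 (AT3G08940) at -2.37 ± 0.39 (-1.52, -2.78). Among loci without a symbol, AT3G02480 rose by 9.0 ± 0.53 and AT1G74670 fell by 7.44 ± 0.44.

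The other 13 lists did not pass in dry C. amara, with adjusted p from 0.0985 to 0.946. They were ethylene, circadian clock, cytosolic ribosome, cell cycle, early stress and touch regulators, hypoxia core, heat shock, stomatal lineage and guard cell markers, salicylate defence, glucosinolate, meristem and floral markers, root markers and reference genes. Hypoxia core genes had a median of -0.13 but a mean of 0.47, and meristem and floral markers a median of 0.49 but a mean of -0.38. Of 15941 genes, 3585 were called, 1915 up and 1670 down. The fit with scan date as a block called 3766, and fits to the first and the second date alone 5311 and 1519.

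In dry C. hirsuta, ABA genes rose alongside jasmonate genes. Most early stress regulators rose too, although the call of their list was lost with an estimated correlation. LEA7 (AT1G52690), a late embryogenesis abundant protein that protects drying cells, rose by 11.52 ± 0.79 (11.76, 11.92; adjusted p = 7.62e-11), and RD26 rose by 7.05 ± 0.45 (7.39, 7.35). NAC055 (AT3G15500), another ABA- and jasmonate-responsive factor, was at least 171-fold higher, as no control was well above background. Of 27 ABA and dehydration genes 23 rose, 23 adjusted over the list alone, with a median of 3.81 (4.03, 3.81; adjusted p = 1.37e-25). Of 21 jasmonate and wounding genes 17 rose, 17 adjusted over the list alone, with a median of 3.17 (2.99, 3.09; adjusted p = 1.60e-16), for example the lipoxygenase LOX4 (AT1G72520) at 6.81 ± 0.58 (7.77, 6.76).

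Early stress and touch regulators, transcription factors and wall genes that respond within minutes to many stimuli, rose in 7 of 10 cases in dry C. hirsuta and in 8 adjusted over the list alone. Their median was 3.31 (3.58, 3.46; adjusted p = 3.16e-08, but adjusted p = 0.0512 with an estimated correlation). The zinc finger genes ZAT6 (AT5G04340) and ZAT10 (AT1G27730) rose by 7.10 ± 0.48 (7.22, 7.67) and 5.47 ± 0.61 (6.44, 5.43), and WRKY40 (AT1G80840) by 6.51 ± 0.56 (6.80, 6.71), although its other probe had the opposite sign. Aquaporins rose in 9 of 15 cases, 9 adjusted over the list alone, with a median of 1.99 (1.36, 1.76; adjusted p = 8.81e-08, but adjusted p = 0.0736 with an estimated correlation), led by TIP2;2 (AT4G17340), a vacuolar water channel, at 4.58 ± 0.62 (4.75, 5.01). Carbon starvation genes rose in 9 of 19 cases, 9 adjusted over the list alone, with a median of 0.83 (0.82, 1.51; adjusted p = 6.72e-06, and adjusted p = 0.0463 with an estimated correlation). Among them the asparagine synthetase ASN1 (AT3G47340) rose by 6.12 ± 0.54 (6.41, 6.41).

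Flavonoid genes rose in 4 of 11 cases and fell in 1, with 5 up and 1 down adjusted over the list alone and a median of 0.77 (0.93, 1.22; adjusted p = 0.0397). That call was lost with an estimated correlation (adjusted p = 0.448), with scan date as a block (adjusted p = 0.0672), and under quantile normalization. TT8 (AT4G09820), a flavonoid regulator, rose by 3.2 ± 0.31 (3.87, 3.17). Auxin and growth genes fell in 11 of 22 cases and rose in 3, with the same counts adjusted over the list alone and a median of -0.74 (-0.76, -0.30; adjusted p = 0.0397), a call lost with an estimated correlation (adjusted p = 0.418) and under quantile normalization. PRE1 fell by 3.43 ± 0.47 (-3.06, -3.11). The hemoglobin gene HB1 (AT2G16060), known to be induced by low oxygen, fell by 3.62 ± 0.44 (-3.39, -3.65), and the replication clamp gene PCNA1 (AT1G07370) by 2.1 ± 0.32 (-1.75, -2.27). The remaining 13 lists did not pass, with adjusted p from 0.0518 to 0.909. Of 15697 genes, 3401 were called, 1582 up and 1819 down, and this order turned in 8 of 24 alternatives, among them 1700 up and 1424 down with the 75th percentile over well detected probes and 1710 and 1677 with scan date as a block. In the fit with scan date as a block 3387 were called, the first and the second date alone gave 3568 and 1119, and the fit without the exchanged arrays gave 4659.

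In dry C. flexuosa the lists that shifted upwards in both parents did so again. LEA7 rose by 11.14 ± 0.79 (11.91, 10.76; adjusted p = 1.84e-10), RD26 by 7.39 ± 0.45 (7.55, 7.26) and GOLS2 by 6.96 ± 0.42 (7.29, 6.79). HAI2 (AT1G07430), a phosphatase that restrains ABA signalling, was at least 69.6-fold higher. Of 30 ABA and dehydration genes 28 rose, 28 adjusted over the list alone, with a median of 4.19 (4.49, 4.35; adjusted p = 3.79e-29). Jasmonate and wounding genes rose in 15 of 22 cases, 17 adjusted over the list alone, with a median of 2.07 (1.47, 2.35; adjusted p = 5.93e-11). LOX3 rose by 6.06 ± 0.55 (5.70, 6.45) and AOC2 (AT3G25770), an allene oxide cyclase of jasmonate synthesis, by 5.19 ± 0.58 (5.35, 5.30). Early stress and touch regulators rose in 8 of 11 cases, 8 adjusted over the list alone, with a median of 2.36 (2.44, 2.69; adjusted p = 3.83e-06, but adjusted p = 0.0556 with an estimated correlation). WRKY40 rose by 5.22 ± 0.56 (5.48, 5.28) and TCH4 (AT5G57560), a touch-induced cell wall enzyme, by 3.59 ± 0.59 (3.36, 4.02).

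Aquaporins rose in 11 of 15 cases in dry C. flexuosa, 11 adjusted over the list alone, with a median of 1.97 (1.94, 1.89; adjusted p = 5.96e-08, but adjusted p = 0.0698 with an estimated correlation), including PIP2;1 at 3.86 ± 0.29 (3.88, 3.81). Carbon starvation genes rose in 10 of 20 cases, 10 adjusted over the list alone, with a median of 1.32 (1.53, 1.47; adjusted p = 2.26e-07). Flavonoid genes rose in 6 of 13 cases, 6 adjusted over the list alone, with a median of 1.31 (0.79, 1.77; adjusted p = 0.000334, but adjusted p = 0.087 with an estimated correlation). Heat shock genes rose in 6 of 12 cases and fell in 1, with the same counts adjusted over the list alone and a median of 1.49 (1.46, 1.36; adjusted p = 0.0240). That call was lost with an estimated correlation (adjusted p = 0.205) and under quantile normalization. MBF1C (AT3G24500), a coactivator of heat responses, rose by 3.95 ± 0.58 (3.90, 3.84).

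Glucosinolate genes, which make the defence compounds of this plant family, fell in 9 of 16 cases in dry C. flexuosa, 11 adjusted over the list alone, with a median of -1.52 (-1.34, -1.59; adjusted p = 1.94e-05). UGT74B1 (AT1G24100), a glucosyltransferase of that pathway, fell by 2.58 ± 0.43 (-2.42, -2.60), a call lost with the scanner files as attached. Cytosolic ribosome genes fell in 5 of 20 cases, 5 adjusted over the list alone, with a median of -0.82 (-0.70, -0.84; adjusted p = 0.0122), a call lost with an estimated correlation (adjusted p = 0.143) and with normexp. EXPA1 fell by 3.75 ± 0.50 (-4.03, -3.52) and MYB60 (AT1G08810), a guard cell regulator, by 2.14 ± 0.27 (-1.99, -2.33). The remaining 11 lists did not pass, with adjusted p from 0.0879 to 0.976, photosynthesis and auxin and growth among them. Of 16986 genes, 3615 were called, 1904 up and 1711 down. Blocking on scan date gave 3636, the first and the second date alone gave 4584 and 1030, and the fit without the exchanged arrays gave 3672. Normexp moved the median of all genes from 0.04 to -0.17.

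**Figure D1:**
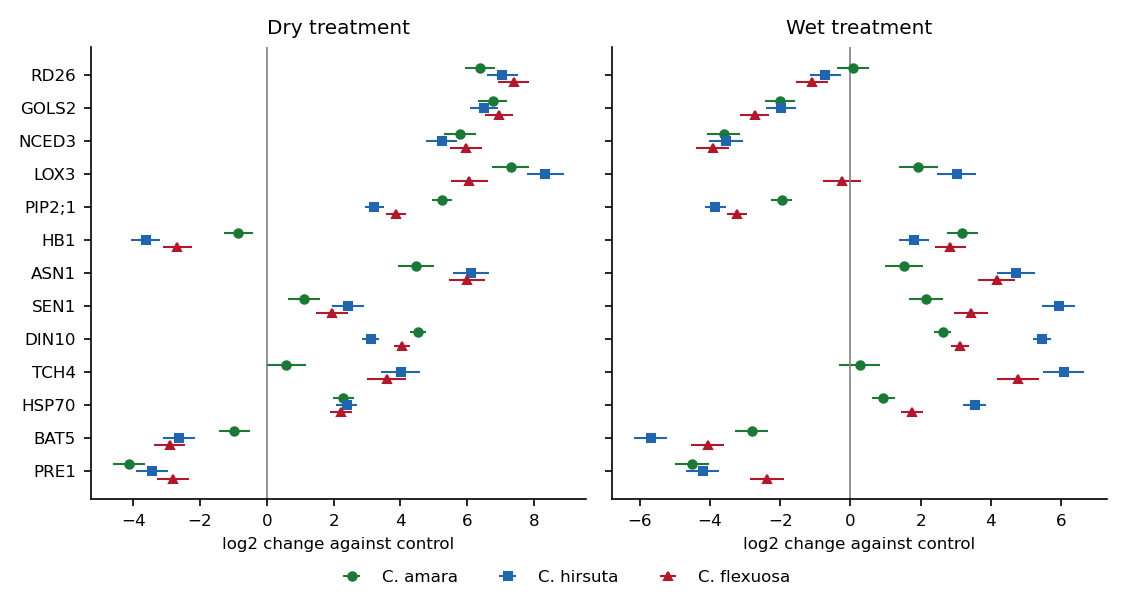
Log2 change against control (x axis) of 13 named genes (y axis) in the dry and the wet panel, with a point for each species and bars for the SE from limma (n = 3 arrays per group). RD26 lies at 6.39, 7.05 and 7.39 in dry C. amara, C. hirsuta and C. flexuosa, and NCED3 rises in dry and falls in wet in each species.

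The wet comparison asked which transcripts changed under water. In C. amara, the carbon starvation and ethylene lists shifted upwards. EXL4 (AT5G09440), an EXORDIUM-like gene of low carbon supply, rose by 2.52 ± 0.32 (2.89, 1.89; adjusted p = 1.62e-05), and SEN1 (AT4G35770), a marker of darkness and sugar starvation, by 2.15 ± 0.48 (2.75, 2.19; adjusted p = 0.00705), a call lost with the scanner files as attached. The organ size genes ARGOS (AT3G59900) and ARL (AT2G44080), both ethylene- or hormone-responsive, rose by 2.53 ± 0.33 (2.89, 2.32) and 2.26 ± 0.38 (3.0, 1.73). Carbon starvation genes rose in 7 of 20 cases, with 10 up and 1 down adjusted over the list alone and a median of 1.2 (1.08, 1.27; adjusted p = 3.52e-08). Ethylene genes rose in 6 of 19 cases and fell in 1, with 7 up and 2 down adjusted over the list alone and a median of 0.89 (0.66, 0.89; adjusted p = 1.28e-06).

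Hypoxia core genes, the common low-oxygen response, rose in 4 of 21 cases in wet C. amara and in 6 adjusted over the list alone. Their median was 0.27 (0.49, -0.01), and the call (adjusted p = 0.00598) was lost with an estimated correlation (adjusted p = 0.216). HB1 rose by 3.19 ± 0.44 (3.74, 2.56; adjusted p = 3.93e-05), a call lost when all probes of a gene were averaged. ADH1 (AT1G77120), the alcohol dehydrogenase of fermentation, chosen after its values were seen, rose by 1.3 ± 0.35 (adjusted p = 0.0253). PIP2;1 fell by 1.96 ± 0.29 (-1.89, -2.03; adjusted p = 9.73e-05), PRE1 by 4.51 ± 0.47 (-4.21, -3.88) and NCED3 by 3.62 ± 0.48 (-2.56, -3.88). Aquaporins fell in 3 of 15 cases, 5 adjusted over the list alone, with a median of -0.52 (-0.28, -0.78; adjusted p = 0.00288, but adjusted p = 0.412 with an estimated correlation). Auxin and growth genes fell in 4 of 23 cases, 5 adjusted over the list alone, with a median of -0.49 (-0.05, -0.53; adjusted p = 0.0422). That call was lost with an estimated correlation (adjusted p = 0.412), with scan date as a block (adjusted p = 0.0604) and under quantile normalization. Photosynthesis genes had 3 of 39 down, 3 adjusted over the list alone, and a median of -0.45 (-0.31, -0.28; adjusted p = 0.0123), a call lost with an estimated correlation (adjusted p = 0.763) and under quantile normalization. The remaining 14 lists did not pass, with adjusted p from 0.0556 to 0.951.

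In wet C. amara 898 of the genes tested were called, 311 up and 587 down. The median of all genes was -0.14, and under quantile normalization, where it was 0.02, 529 rose and 545 fell, while a 75th percentile over well detected probes gave 448 up and 479 down at a median of 0.07. Relative to the median of all genes, the carbon starvation and ethylene medians were higher and the NCED3, PRE1 and PIP2;1 changes lower. The blocked fit gave 1051, the first date alone 1048 and the second 23, where 1485 had an unadjusted p under 0.05. Without control replicate 1 the count was 3457, without control replicate 2 or 3 it was 458 or 514, and without wet replicate 1 or 2 it was 415 or 460.

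In wet C. hirsuta carbon starvation, heat shock and early stress genes rose. TCH4 rose by 6.08 ± 0.59 (6.52, 5.98; adjusted p = 1.07e-07), SEN1 by 5.93 ± 0.48 (6.0, 6.09; adjusted p = 7.09e-09) and HSP17.6B (AT2G29500), a small heat shock chaperone, by 5.29 ± 0.52 (4.25, 5.73; adjusted p = 1.14e-07). Carbon starvation genes rose in 11 of 19 cases, 11 adjusted over the list alone, with a median of 1.65 (1.68, 1.52; adjusted p = 2.37e-12), for example ASN1 at 4.72 ± 0.54 (5.26, 4.52) and BCAT2 (AT1G10070), an aminotransferase of branched-chain amino acids, at 3.95 ± 0.33 (4.78, 3.38). Heat shock genes rose in 10 of 12 cases, 10 adjusted over the list alone, with a median of 2.41 (2.43, 2.46; adjusted p = 9.43e-09). Early stress and touch regulators rose in 7 of 10 cases, 8 adjusted over the list alone, with a median of 2.46 (2.78, 2.93; adjusted p = 4.91e-09, and adjusted p = 0.0400 with an estimated correlation). Ethylene genes rose in 6 of 17 cases, 6 adjusted over the list alone, with a median of 0.81 (1.2, 0.99; adjusted p = 1.21e-06), including the response factor ERF104 (AT5G61600) at 3.45 ± 0.54 (4.48, 3.25).

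Hypoxia core genes rose in 3 of 20 cases in wet C. hirsuta, with 3 up and 1 down adjusted over the list alone and a median of 0.72 (0.57, 0.37; adjusted p = 0.0172). That call was lost with an estimated correlation (adjusted p = 0.33) and without the exchanged arrays. HUP54 (AT4G27450), a low-oxygen marker, rose by 1.93 ± 0.35 (2.32, 1.82; adjusted p = 0.000414), while ADH1, chosen after its values were seen, had a change of -0.26 ± 0.35 (adjusted p = 0.616). Glucosinolate genes fell in 9 of 17 cases and rose in 1, with 11 down and 1 up adjusted over the list alone and a median of -1.35 (-1.65, -1.23; adjusted p = 1.74e-05). The transporter BAT5 (AT4G12030) and the chain-elongation enzyme MAM1 (AT5G23010) of that pathway fell by 5.70 ± 0.47 (-4.72, -6.63) and 3.80 ± 0.46 (-2.78, -4.74). Flavonoid genes fell in 8 of 11 cases and rose in 1, with the same counts adjusted over the list alone and a median of -1.91 (-1.33, -1.97; adjusted p = 0.0023). That call was lost with an estimated correlation (adjusted p = 0.205) and with a stricter filter. The anthocyanin regulator PAP1 (AT1G56650) fell by 3.36 ± 0.41 (-3.05, -3.47), a call lost with the scanner files as attached. PIP2;1 fell by 3.85 ± 0.29 (-3.26, -3.85) and NCED3 by 3.55 ± 0.48 (-2.90, -3.47), although the aquaporin list did not pass (adjusted p = 0.147). Photosynthesis genes had 3 of 39 down, no member adjusted over the list alone, and a median of -0.54 (-0.27, -0.52; adjusted p = 0.012), a call lost with an estimated correlation (adjusted p = 0.763) and under quantile normalization. The remaining 12 lists had adjusted p from 0.104 to 0.720.

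In wet C. hirsuta 2415 genes were called, 947 up and 1468 down. The median of all genes was -0.21, and this direction depended on the scaling, as quantile normalization gave 1132 up and 869 down at a median of -0.04 and the 75th percentile over well detected probes 1344 up and 655 down at 0.18. The falls of BAT5, MAM1, PIP2;1 and NCED3 and the carbon starvation and heat shock medians all exceeded these shifts. In the fit with scan date as a block 2278 were called, the first and the second date alone gave 1414 and 520, and without the exchanged arrays 5004 were called. Without control replicate 1 the count was 4970 and without control replicate 3 it was 1339.

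In wet C. flexuosa the carbon starvation, ethylene, hypoxia core and early stress lists shifted upwards. TCH4 rose by 4.78 ± 0.59 (4.51, 5.29; adjusted p = 7.23e-06), ASN1 by 4.16 ± 0.54 (5.33, 3.3) and SEN1 by 3.44 ± 0.48 (4.17, 3.35). Carbon starvation genes rose in 9 of 20 cases, 10 adjusted over the list alone, with a median of 1.18 (1.2, 1.17; adjusted p = 3.65e-11). Ethylene genes rose in 6 of 19 cases, 8 adjusted over the list alone, with a median of 1.00 (0.84, 1.40; adjusted p = 1.16e-08), including ARL at 2.48 ± 0.38 (2.71, 2.60) and ARGOS at 2.3 ± 0.33 (2.47, 2.43). Hypoxia core genes rose in 4 of 23 cases, 4 adjusted over the list alone, with a median of 1.05 (1.15, 0.68; adjusted p = 4.25e-06, and adjusted p = 0.0364 with an estimated correlation). HUP54 rose by 2.33 ± 0.35 (2.92, 2.17; adjusted p = 8.62e-05), and ADH1, chosen after its values were seen, by 1.67 ± 0.35 (adjusted p = 0.0028). Early stress and touch regulators rose in 4 of 11 cases, 7 adjusted over the list alone, with a median of 1.40 (1.55, 1.47; adjusted p = 1.51e-07, and adjusted p = 0.0347 with an estimated correlation). Heat shock genes rose in 4 of 12 cases, 4 adjusted over the list alone, with a median of 0.70 (0.29, 1.81; adjusted p = 0.00928), a call lost with an estimated correlation (adjusted p = 0.139) and under quantile normalization. HSFA7A (AT3G51910), a heat shock factor, rose by 3.10 ± 0.27 (2.77, 3.49; adjusted p = 5.36e-08).

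Glucosinolate genes fell in 9 of 16 cases in wet C. flexuosa and rose in 4, with the same counts adjusted over the list alone and a median of -1.55 (-1.43, -1.08; adjusted p = 0.00634). That call was lost with an estimated correlation (adjusted p = 0.143) and under quantile normalization. BAT5 fell by 4.06 ± 0.47 (-3.63, -4.01) and MAM1 by 2.84 ± 0.46 (-2.43, -3.29), both of the methionine-derived branch. CYP79B2 (AT4G39950) and CYP79B3 (AT2G22330), which open the tryptophan-derived branch and were chosen here after their values were seen, rose by 1.98 ± 0.45 (adjusted p = 0.00534) and 1.71 ± 0.44 (adjusted p = 0.0166). ABA and dehydration genes fell in 5 of 30 cases, with 5 down and 1 up adjusted over the list alone and a median of -0.49 (-0.17, -0.62; adjusted p = 0.000271, and adjusted p = 0.0342 with an estimated correlation), with NCED3 at -3.93 ± 0.48 (-3.09, -4.70). Flavonoid genes fell in 5 of 13 cases and rose in 1, with 5 down and 2 up adjusted over the list alone and a median of -0.90 (-0.99, -0.83; adjusted p = 0.0284), a call lost with an estimated correlation (adjusted p = 0.352) and with normexp. Aquaporins fell in 3 of 15 cases, 3 adjusted over the list alone, with a median of -0.22 (-0.12, -0.50; adjusted p = 0.0023, but adjusted p = 0.397 with an estimated correlation), and PIP2;1 fell by 3.23 ± 0.29 (-3.19, -3.32). Clock genes fell in 5 of 21 cases and rose in 3, with the same counts adjusted over the list alone and a median of -0.53 (-0.37, -0.68; adjusted p = 0.00598), and the 20 cytosolic ribosome genes, with no called member, had a median of -0.43 (-0.45, -0.42; adjusted p = 0.0286). With an estimated correlation these calls were lost, with adjusted p = 0.224 for the clock and adjusted p = 0.213 for the ribosome, and both were lost with normexp. The remaining 9 lists had adjusted p from 0.0574 to 0.923. In all 1026 genes were called, 578 up and 448 down. Blocking on scan date gave 1155, the first and the second date alone gave 2121 and 131, and the fit without the exchanged arrays gave 1102. The median of all genes was 0.01, and 0.11 under the 75th percentile over well detected probes and -0.14 with normexp.

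**Figure D2:**
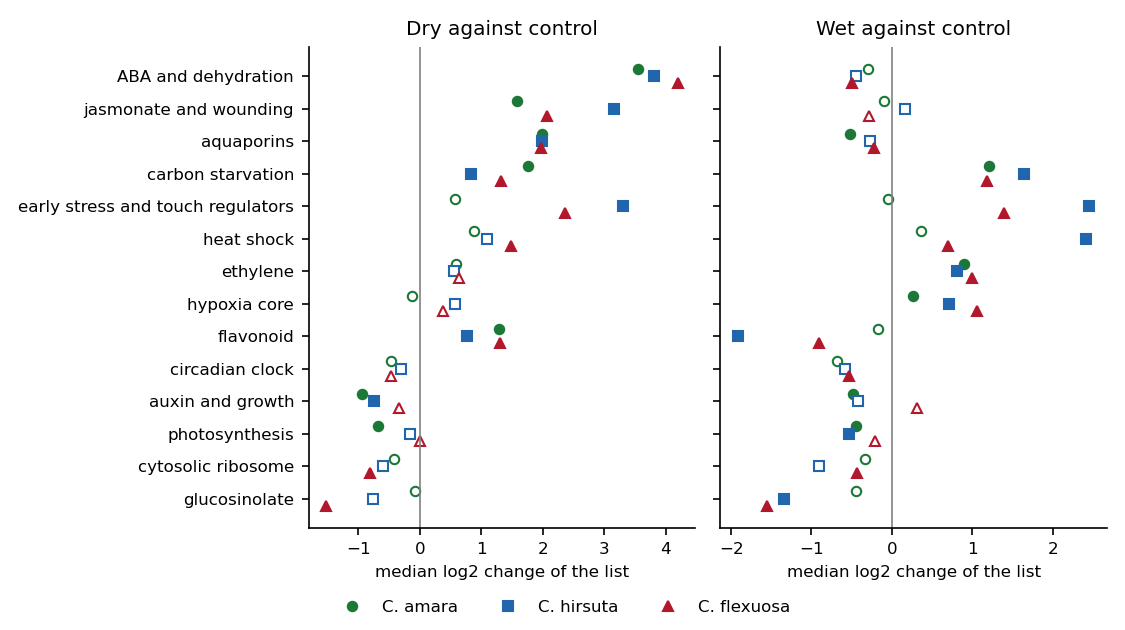
Median log2 change (x axis) of 14 gene lists (y axis) against control in dry and wet seedlings of each species, with filled points where camera gave an adjusted p under 0.05 at the preset correlation and open points elsewhere. ABA and dehydration genes lie at 3.55, 3.81 and 4.19 in dry C. amara, C. hirsuta and C. flexuosa, and carbon starvation genes at 1.2, 1.65 and 1.18 in wet.

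Dry and wet seedlings, both taken at 2 h, were compared directly. Only the dry seedlings were severed, so this comparison holds cutting and submergence as well as drying. ABA genes were higher in dry seedlings of all 3 species. NCED3 was higher by 9.39 ± 0.48 (9.50, 9.17), 8.78 ± 0.48 (8.88, 8.57) and 9.88 ± 0.48 (9.63, 10.38) in C. amara, C. hirsuta and C. flexuosa. HB1 was lower, at -4.04 ± 0.44 (-4.56, -3.0), -5.44 ± 0.44 (-5.76, -4.79) and -5.52 ± 0.44 (-5.68, -5.20), with the C. amara call lost when all probes of a gene were averaged. Of the ABA and dehydration genes 25 of 27, 23 of 27 and 29 of 30 were higher, with medians of 3.61, 4.37 and 4.85 (adjusted p = 4.74e-25, 1.37e-25 and 9.7e-39). Jasmonate and wounding genes had medians of 2.13, 3.25 and 2.45 (adjusted p = 1.67e-07, 2.53e-15 and 1.01e-14), and aquaporins medians of 2.51, 1.73 and 2.13 (adjusted p = 3.58e-11, 3.26e-10 and 2.37e-12). These 9 list results also passed with an estimated correlation.

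Flavonoid genes were higher in dry than in wet seedlings, with medians of 1.25, 2.59 and 2.36 (adjusted p = 0.00462, 4.79e-06 and 2.51e-06). With an estimated correlation these became adjusted p = 0.194, 0.0505 and 0.0315. Glucosinolate genes were higher in dry C. hirsuta by a median of 1.08 (adjusted p = 0.00177, but adjusted p = 0.084 with an estimated correlation) and lower in dry C. flexuosa at a median of -1.02. The latter call (adjusted p = 0.0476) was lost with an estimated correlation (adjusted p = 0.33), with scan date as a block (adjusted p = 0.0706), with the replicate block (adjusted p = 0.0710) and under quantile normalization. In C. hirsuta the ethylene list, with a median of -0.50 (adjusted p = 0.0604), and the photosynthesis list, with a median of 0.39 (adjusted p = 0.152), passed only with the replicate block (adjusted p = 0.0489 and 0.0426). Heat shock genes were lower in dry C. hirsuta at a median of -1.3 (adjusted p = 0.0023, but adjusted p = 0.143 with an estimated correlation), and HSP17.6B was lower, at -4.03 ± 0.52 (-3.70, -4.69). In C. amara auxin and growth genes had a median of -0.45 (adjusted p = 0.0277) and photosynthesis genes of -0.31 (adjusted p = 0.0356), which became adjusted p = 0.354 and 0.781 with an estimated correlation. The genes called were 3263 in C. amara, 2831 in C. hirsuta and 2763 in C. flexuosa, with 3647, 3113 and 3010 in the fit with scan date as a block. The first date alone gave 4853, 3171 and 3193 and the second 576, 876 and 679. In C. amara 2052 were higher and 1211 lower at a median of all genes of 0.09, against 1711 and 1731 at -0.10 under quantile normalization. In C. hirsuta 1635 were higher and 1196 lower at a median of 0.10, against 1290 and 1529 at -0.14 with the 75th percentile over well detected probes.

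Responses were compared across species over all genes tested in both, although genes are not independent replicates. The dry changes correlated at Pearson's r of 0.825 between C. flexuosa and C. hirsuta (15093 genes), 0.695 between C. flexuosa and C. amara (15242 genes) and 0.652 between C. amara and C. hirsuta (14113 genes). With scan date as a block these were 0.814, 0.683 and 0.640, and Spearman's rho was 0.803, 0.622 and 0.566. Changes in C. amara correlated least between dates, which can lower its correlations, so this order does not rank likeness. The wet changes correlated at 0.667, 0.566 and 0.546 for the same pairs, with 0.620, 0.518 and 0.491 in the blocked fit. Among 13966 genes tested in all 3 species, 705 rose and 693 fell in all 3 dry comparisons, against 18.7 and 21.7 if calls were independent. In wet the counts were 115 up and 177 down, against 0.617 and 1.59.

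Differences between species in a response were tested as interactions. Weak probe binding can shrink a change, so a difference may partly reflect it. Between dry C. amara and C. hirsuta the early stress regulators had the largest median difference of the lists. WRKY40 rose less in C. amara, with a difference of -5.88 ± 0.79 (-4.27, -7.27; adjusted p = 2.85e-05), as did ZAT6 at -5.16 ± 0.68 (-5.43, -6.34; adjusted p = 2.27e-05) and ZAT10 at -5.29 ± 0.86 (-4.19, -6.46; adjusted p = 0.000269). In C. amara itself, outside the rule for naming genes, WRKY40 had a dry change of 0.63 ± 0.56 (2.53, -0.56; adjusted p = 0.468) and ZAT10 of 0.18 ± 0.61 (2.25, -1.02; adjusted p = 0.882), with dry and control arrays that overlapped. Over the 11 early stress and touch regulators tested in dry C. amara the median change was 0.57 (1.55, -0.34) with 2 called up, and with control replicate 1 as the only control it was 1.33 with 5 called up. Of 10 early stress and touch regulators 7 were lower in C. amara, with a median difference of -3.19 (-1.91, -3.98; adjusted p = 3.43e-08, but adjusted p = 0.0512 with an estimated correlation). The C. amara controls were uneven in these genes, with replicate 3 above replicate 1 by a median of 1.96, and with replicate 1 as the only C. amara control the median difference was -1.62 with 4 lower (adjusted p = 9.11e-06, but adjusted p = 0.173 with an estimated correlation). Jasmonate and wounding genes were lower in 7 of 21 cases, with a median of -1.1 (-1.3, -1.19; adjusted p = 3.44e-07, and adjusted p = 0.0248 with an estimated correlation). Photosynthesis genes had a median of -0.38 (adjusted p = 0.000265) and clock genes of -0.18 (adjusted p = 0.0216), which became adjusted p = 0.605 and 0.472 with an estimated correlation. GH3.3 (AT2G23170), which conjugates auxin, was higher by 3.95 ± 0.54 (3.62, 3.75; adjusted p = 3.22e-05) and HB-12 by 2.94 ± 0.42 (3.25, 2.42). In all 1006 genes differed, 555 higher and 451 lower in C. amara, against 647 and 805 with the 75th percentile over well detected probes. The blocked fit gave 1517, the first and the second date alone 2888 and 37, the fit without the exchanged arrays 1596, and leaving out C. hirsuta control replicate 1 alone 1628.

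The dry response of C. flexuosa was above that of C. amara in early stress regulators when all C. amara controls were used, with WRKY40 higher by 4.59 ± 0.79 (2.96, 5.84; adjusted p = 0.00104). Of 11 members 5 were higher, with a median of 2.32 (0.89, 3.0; adjusted p = 2.49e-06, but adjusted p = 0.0524 with an estimated correlation). With C. amara control replicate 1 alone, 2 were higher and the median was 1.12 (adjusted p = 0.000805, but adjusted p = 0.246 with an estimated correlation). Glucosinolate genes were lower in 4 of 14 cases, with a median of -1.56 (-1.47, -1.70; adjusted p = 2.48e-05, and adjusted p = 0.0297 with an estimated correlation). HB-12 rose less in C. flexuosa, with a difference of -2.05 ± 0.42 (-2.15, -2.02; adjusted p = 0.00485). Auxin and growth genes had a median of 0.55 (adjusted p = 0.000479) and photosynthesis genes of 0.51 (adjusted p = 5.89e-05), which became adjusted p = 0.117 and 0.59 with an estimated correlation. In all 593 genes differed, 314 higher and 279 lower in C. flexuosa. In the fit with scan date as a block 952 were called, and in the first and the second date alone 2607 and 3. Without C. amara control replicate 1 the count was 974, and without C. flexuosa dry replicate 1, 2 or 3 it was 390, 392 or 395.

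Single genes also differed in dry response between C. flexuosa and C. hirsuta. PAP1 was higher in C. flexuosa by 4.26 ± 0.58 (4.29, 3.79; adjusted p = 9.66e-05), a call lost with the scanner files as attached, and GH3.5 (AT4G27260), another auxin-conjugating enzyme, lower, at -3.57 ± 0.43 (-3.98, -3.12; adjusted p = 1.87e-05). The flavonoid list, which holds PAP1, did not pass (adjusted p = 0.130). Glucosinolate genes had a median of -0.82 (-0.44, -1.3; adjusted p = 8.47e-07) and jasmonate and wounding genes of -0.77 (-1.2, -0.83; adjusted p = 3.60e-07), which kept adjusted p = 0.0185 and 0.0248 with an estimated correlation. Auxin and growth genes had a median of 0.71 (adjusted p = 0.0185) and early stress regulators of -0.57 (adjusted p = 0.0476), which became adjusted p = 0.338 and 0.59. In all 213 genes differed, 118 higher and 95 lower, against 189 and 264 with the 75th percentile over well detected probes. Blocking on scan date gave 382, the first and the second date alone 936 and 2, and leaving out C. hirsuta control replicate 1 gave 384.

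In the wet response too, C. amara lay below C. hirsuta in early stress and heat shock genes when all controls were used. TCH4 differed by -5.82 ± 0.84 (-4.12, -6.93; adjusted p = 0.000249), ZAT12 (AT5G59820), an oxidative stress zinc finger, by -5.29 ± 0.74 (-4.83, -5.42; adjusted p = 0.000166) and HSP17.6B by -4.99 ± 0.73 (-4.31, -6.0; adjusted p = 0.000279). TCH4 in wet C. amara had a change of 0.26 ± 0.59 (adjusted p = 0.819). Of 10 early stress and touch regulators 6 were lower, 8 adjusted over the list alone, with a median of -3.24 (-2.76, -3.56; adjusted p = 1.05e-11, and adjusted p = 0.0248 with an estimated correlation). With replicate 1 as the only C. amara control 3 were lower and the median was -2.04 (adjusted p = 1.78e-08), and the call with an estimated correlation was lost (adjusted p = 0.0705). Heat shock genes were lower in 5 of 10 cases, with a median of -2.24 (-1.69, -2.86; adjusted p = 2.01e-10, and adjusted p = 0.00233 with an estimated correlation), and carbon starvation genes in 5 of 18, with a median of -1.04 (-1.19, -0.98; adjusted p = 3.16e-07, and adjusted p = 0.0364 with an estimated correlation). Flavonoid genes had a median of 1.31 (adjusted p = 0.00153) and glucosinolate genes of 0.67 (adjusted p = 0.000788), which became adjusted p = 0.172 and 0.0654 with an estimated correlation. In all 344 genes differed, 167 higher and 177 lower in C. amara, against 251 and 409 with the 75th percentile over well detected probes, which moved the median of all genes from 0.13 to -0.05. The blocked fit gave 663, the first date alone 290 and the second 0, where limma gave 1172 at an unadjusted p under 0.05. Without C. amara control replicate 1 the count was 1004 and without C. hirsuta control replicate 1 it was 1335, while 219, 220 and 212 were called without C. hirsuta control replicate 2, wet replicate 2 and wet replicate 3.

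With all controls, the wet response of C. flexuosa was above that of C. amara in early stress regulators, with 3 of 11 higher and a median of 2.41 (1.35, 2.58; adjusted p = 4.97e-09, and adjusted p = 0.0248 with an estimated correlation). Against C. amara control replicate 1 alone, no member was called and the median was 0.99 (adjusted p = 6.20e-06), and the call with an estimated correlation was lost (adjusted p = 0.106). TCH4 was higher by 4.52 ± 0.84 (2.1, 6.24; adjusted p = 0.0117), a call lost without C. flexuosa control replicate 2 (4.23) or wet replicate 3 (4.27). Heat shock genes had a median of 0.98 (adjusted p = 0.0046), auxin and growth genes of 0.84 (adjusted p = 0.000337), ABA and dehydration genes of -0.42 (adjusted p = 0.00598) and flavonoid genes of -0.93 (adjusted p = 0.0117). With an estimated correlation these became adjusted p = 0.0527, 0.106, 0.0891 and 0.263. In all 73 genes differed, 54 higher and 19 lower. In the fit with scan date as a block 162 were called, the first date alone 406 and the second 0, where limma gave 521 at an unadjusted p under 0.05. Without C. amara control replicate 1 the count was 454, without C. amara control replicate 3 it was 35, and without C. amara wet replicate 1 or 3 it was 29 or 39. Without C. flexuosa control replicate 1 or 2 it was 25 or 23, and without C. flexuosa wet replicate 1, 2 or 3 it was 28, 28 or 21.

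Between wet C. flexuosa and C. hirsuta the glucosinolate and heat shock lists differed. CYP79B3 was higher in C. flexuosa by 3.84 ± 0.63 (3.35, 4.63; adjusted p = 0.00175) and SOT16 (AT1G74100), a sulfotransferase of glucosinolate synthesis, by 2.26 ± 0.37 (2.88, 1.96; adjusted p = 0.00175). HSP17.6B was lower, at -5.46 ± 0.73 (-4.72, -5.66; adjusted p = 0.000219). Glucosinolate genes had a median of 0.92 (0.66, 1.19; adjusted p = 0.000165) and heat shock genes of -1.26 (-1.47, -0.28; adjusted p = 2.75e-06), which kept adjusted p = 0.0446 and 0.0248 with an estimated correlation. Carbon starvation genes had a median of -0.55 (adjusted p = 4.36e-06), auxin and growth genes of 0.72 (adjusted p = 0.000782), early stress regulators of -0.51 (adjusted p = 0.00707), jasmonate and wounding genes of -0.18 (adjusted p = 0.0027) and ABA and dehydration genes of -0.25 (adjusted p = 0.0476). With an estimated correlation these became adjusted p = 0.055, 0.134, 0.431, 0.163 and 0.303, and the ABA call was also lost with scan date as a block (adjusted p = 0.0513). In all 98 genes differed, 58 higher and 40 lower, at a median of all genes of 0.24 that the 75th percentile over well detected probes moved to -0.05. Blocking on scan date gave 180, the first date alone 494 and the second 0, where limma gave 680 at an unadjusted p under 0.05. The fit without the exchanged arrays gave 379, with 109 higher and 270 lower. Without C. hirsuta control replicate 1 the count was 621, with 243 higher and 378 lower, and without C. hirsuta wet replicate 1 it was 60, and without C. flexuosa wet replicate 1, 2 or 3 it was 57, 56 or 64.

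**Figure D3:**
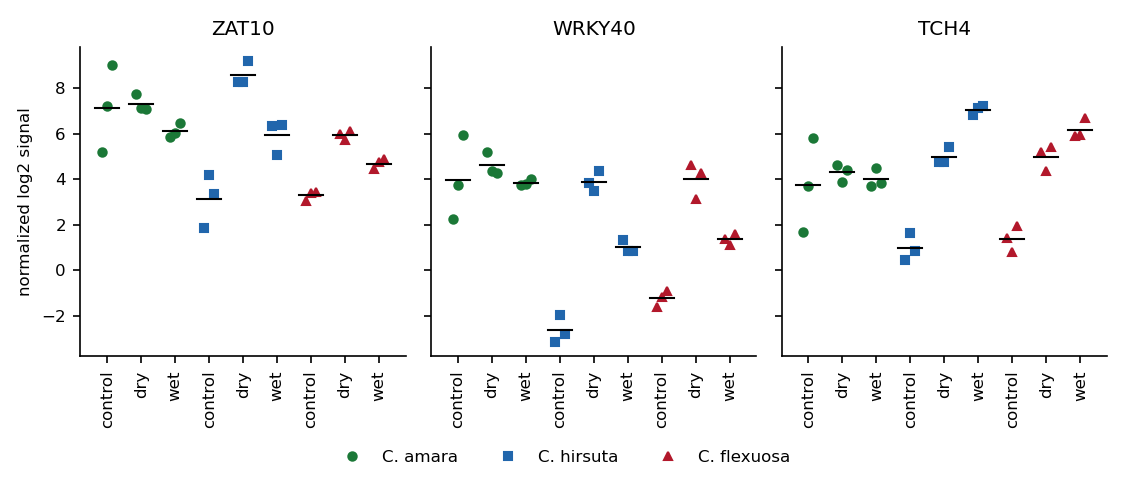
Normalized log2 signal (y axis) of ZAT10, WRKY40 and TCH4 on each array, by species and treatment (x axis), with a point per array and a bar at the mean of 3 arrays. The 3 genes rise in dry C. hirsuta and C. flexuosa, while their changes of 0.18, 0.63 and 0.57 in dry C. amara were not called with all 3 controls. With C. amara control replicate 1 as the only control, 5 of the 11 tested members of their list were called up there.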

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

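The tests of the early stress regulators and of the exchanged scanner files, and the share of all genes in which C. flexuosa lay nearer C. hirsuta, were chosen only after those results were seen. The differences between species in a response are given for a closer look because the interaction itself was called. The dry response differed in 1006 genes between C. amara and C. hirsuta, in 593 between C. flexuosa and C. amara and in 213 between C. flexuosa and C. hirsuta. The wet response differed in 344, 73 and 98 genes for the same pairs.

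Among 120 tests of gene lists for such differences 29 passed, and 10 of them with an estimated correlation. In dry C. amara minus C. hirsuta the medians were -3.19 for early stress and touch regulators, -1.10 for jasmonate and wounding, -0.38 for photosynthesis and -0.18 for the circadian clock. In dry C. flexuosa minus C. amara they were 2.32 for early stress and touch regulators, 0.55 for auxin and growth, 0.51 for photosynthesis and -1.56 for glucosinolate genes. In dry C. flexuosa minus C. hirsuta they were 0.71 for auxin and growth, -0.57 for early stress and touch regulators, -0.77 for jasmonate and wounding and -0.82 for glucosinolate genes. In wet C. amara minus C. hirsuta they were -3.24 for early stress and touch regulators, -2.24 for heat shock, -1.04 for carbon starvation, 0.67 for glucosinolate and 1.31 for flavonoid genes. In wet C. flexuosa minus C. amara they were 2.41 for early stress and touch regulators, 0.98 for heat shock, 0.84 for auxin and growth, -0.42 for ABA and dehydration and -0.93 for flavonoid genes. In wet C. flexuosa minus C. hirsuta they were 0.92 for glucosinolate, 0.72 for auxin and growth, -0.18 for jasmonate and wounding, -0.25 for ABA and dehydration, -0.51 for early stress and touch regulators, -0.55 for carbon starvation and -1.26 for heat shock genes.

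Probes without a locus, which no comparison of genes used, were called in every treatment. In dry seedlings 176 of 1953 were called in C. amara, 144 of 1880 in C. hirsuta and 179 of 2046 in C. flexuosa, and in wet seedlings 25, 70 and 25.

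The smaller change of early stress and touch regulators in C. amara, with medians of -3.19 in dry and -3.24 in wet against C. hirsuta, came with uneven controls. Control replicate 3 minus control replicate 1 had a median of 1.96 over these genes in C. amara, against 0.33 in C. hirsuta and 0.38 in C. flexuosa. For control replicate 2 minus control replicate 1 it was 0.62 in C. amara, 1.02 in C. hirsuta and 0.19 in C. flexuosa. The SD of the 3 controls had a median of 1.53 in C. amara, 0.60 in C. hirsuta and 0.36 in C. flexuosa. These medians do not settle which C. amara control was unusual. With the C. amara control of the first scan date as its only control the dry difference was -1.62 (4 of 10 genes lower, adjusted p = 9.11e-06, but adjusted p = 0.173 with an estimated correlation) and the wet difference -2.04 (3 of 10, adjusted p = 1.78e-08, but adjusted p = 0.0705 with an estimated correlation), and within the first date the dry difference was -1.91 and within the second -3.98. With that control alone 5 of these genes were called up in dry C. amara, at a median of 1.33, and the difference C. flexuosa minus C. amara went from 2.32 to 1.12 in dry and from 2.41 to 0.99 in wet. The values on both dates argue against scan date as the whole of the difference, although the first-date value rests on a single control per species, in C. hirsuta an exchanged array. Raised controls stay open, since a single control array and these tests cannot decide. Control signal was higher in C. amara than in C. hirsuta by a median of 2.96 (quartiles 0.27 and 3.88) and dry signal by 0.08. Weak probe binding in C. amara needs lower signal, but with so wide a spread and no probe sequences it stays open too. A weaker induction in C. amara stays open as a hypothesis, as do plants that were already stimulated before the controls were taken, which no array here can test.

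Scanner files of C. flexuosa control replicate 1 and C. hirsuta control replicate 1 held each other's columns of the value table. Assigned by the value table, the lowest correlation of either array with its own species exceeded the highest with another species by 0.0219. Assigned as attached, the mean correlation with the own species minus the highest mean with another was -0.0985 or lower for both arrays, which argues against an exchange of the value-table columns. Both values are consistent with scanner files exchanged at deposit, and no biological explanation was tested.

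Among 1001 genes whose dry response differed between C. amara and C. hirsuta and that were tested in C. flexuosa, the C. flexuosa change lay nearer C. hirsuta in 63.4%. Restricted to the first scan date, which holds only control replicate 1 of C. amara, the share was 61.6%. The genes were chosen with all controls, that replicate included, so this share cannot decide whether uneven C. amara controls are the cause. Where the probe was at least 2-fold brighter in C. amara the share was 47.5% of 255 genes, and where it was brighter in C. hirsuta 71.8% of 287. Brightness depends on expression as well as on binding, so this sorting is rough. The shares are consistent with arrays that read mainly the better binding gene copy of the tetraploid, and a response of C. flexuosa that is more like that of C. hirsuta stays open beside it, since the arrays cannot separate the copies.

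For each comparison of 3 arrays with 3 there are 10 splits, too few for a share under 0.05. Dry against control gave 3585 genes in C. amara, where 1 of the splits, the real grouping itself, gave as many and the highest other gave 5, 3401 in C. hirsuta with 1 as many and 2940 as the highest other, and 3615 in C. flexuosa with 1 as many and 0 as the highest other in limma. The split of 2940 followed the scan date, and the blocked value was 3387. Wet against control gave 898 genes in C. amara, where 2 of the 10 splits gave as many. The other of them gave 3555, several times the real count, and followed the scan date, which points to a structure of the samples by date, and the blocked value was 1051 with 1048 and 23 within dates. Wet against control gave 2415 in C. hirsuta with 1 as many and 350 as the highest other, and 1026 in C. flexuosa with 1 as many and 6 as the highest other. Dry against wet gave 3263, 2831 and 2763 genes, with 1 split as many in each and 4, 0 and 0 as the highest others. In each of these, 4 splits parted all 3 same-number pairs as the real grouping does, and the others of them gave 0 genes in limma.

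For the differences between species, 100 splits within species were counted. At these counts chance was not excluded, but most splits with as many genes hold the real responses, so they do not measure chance alone and the question stays open. As many genes as in the real grouping were given by 10 splits for dry C. amara minus C. hirsuta (real 1006, highest other 5017), by 10 for dry C. flexuosa minus C. amara (593, 5720) and by 12 for dry C. flexuosa minus C. hirsuta (213, 6055). In wet they were given by 16 for C. amara minus C. hirsuta (344, 6210), by 16 for C. flexuosa minus C. amara (73, 5079) and by 10 for C. flexuosa minus C. hirsuta (98, 3669). In all the highest others, most arrays put in the treated group were truly treated in a species, and most were controls in the other. The difference then held part or all of a sum of responses, a structure of the samples rather than noise. Of the 9, 9 and 11 other splits with as many in dry, 7, 9 and 10 were of this kind, and of the 15, 15 and 9 in wet, 10, 8 and 9. Among the 50, 51 and 52 other splits in dry that were not of this kind 2, 0 and 1 gave as many, and among the 50, 55 and 52 in wet 5, 7 and 0.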

How the results depend on the processing

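Single-date fits, scan blocks within species, for gene lists and similarities, and both fits for exchanged arrays were chosen after the data were seen. Named genes gave 239 results and 5937 values under the alternatives, of which 5431 were the same in direction and call, 504 over 122 results were no longer called, 0 became called and 2 changed sign. Gene lists gave 300 results and 3600 values, of which 3373 were the same, 146 over 52 results no longer passed, 81 over 30 results came to pass and 0 changed sign. JAZ2 (AT1G74950) in wet C. flexuosa was 0.077 with the scanner files as attached against -1.69, and EXPA5 (AT3G29030) there was 0.028 with the mean of all probes against -1.46. The exchange of a control array accounts for the former and the opposite sign of the other probe for the latter. With an estimated correlation 42 gene list results passed against 94, which changes only the correlation assumed between genes of a list. For the other changes of counts below the cause was not tested. Fits that leave out arrays have fewer samples, yet several of them called more genes. Counts follow in the order C. amara, C. hirsuta and C. flexuosa for treatments and C. amara minus C. hirsuta, C. flexuosa minus C. amara and C. flexuosa minus C. hirsuta for differences.

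On the second scan date alone dry gave 1519, 1119 and 1030 genes, wet 23, 520 and 131, dry against wet 576, 876 and 679, the dry differences 37, 3 and 2, and the wet differences 0 each in limma, where 1172, 521 and 680 genes had an unadjusted p under 0.05. On the first date alone wet gave 1414 in C. hirsuta and 2121 in C. flexuosa, the dry differences 2888, 2607 and 936, and the wet differences 406 for C. flexuosa minus C. amara and 494 for C. flexuosa minus C. hirsuta. With scan date as a block the dry differences were 1517, 952 and 382 and the wet differences 663, 162 and 180, and with the block within species 1540, 947 and 400, and 570, 138 and 148. With slide as a block they were 1724, 989 and 837 in dry and 955, 429 and 333 in wet.

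Of 18 same-number pairs of a control with a treated array, 9 had deviations that correlated above 0.1, and the range was -0.395 to 0.406. Control replicate 2 was scanned on the second date and treated replicate 2 on the first, so these pairs cannot show whether numbers pair controls. Between groups of a species, deviations correlated at a mean of 0.198 within a date and -0.185 across dates. Of 27 arrays 16 correlated best with their own number. For dry against wet, where same-number arrays correlated, the replicate block gave 3546, 3028 and 2911 genes. That block ended the call of the glucosinolate list in C. flexuosa and added calls of the ethylene and photosynthesis lists in C. hirsuta. It changed no other call of a list or named gene there. With the replicate block the wet difference C. amara minus C. hirsuta gave 558 genes, and the other counts were within 1.5 times. Only arrays of the species compared gave 329 genes in wet C. amara, 606 for the dry and 159 for the wet difference C. amara minus C. hirsuta.

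The scanner files as attached gave 447 genes in wet C. amara, 447, 266 and 91 for the dry differences and 103, 12 and 24 for the wet differences. Correlations of responses across genes were then 0.611 for dry C. amara and C. hirsuta, 0.716 for dry C. flexuosa and C. hirsuta, and 0.491 and 0.492 for wet C. flexuosa with C. amara and with C. hirsuta. Without both exchanged arrays wet C. hirsuta gave 5004, the dry difference C. amara minus C. hirsuta 1596, and the wet differences 1295, 42 and 379, with correlations of 0.609 for dry C. amara and C. hirsuta and 0.816 for dry C. flexuosa and C. hirsuta.

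Quantile normalization gave 1113 and 522 for the dry differences of C. flexuosa and 625, 253 and 178 for the wet differences, with a correlation of 0.640 for dry C. amara and C. hirsuta. The 75th percentile over probes well above background on all arrays gave 1004 and 453, and 660, 224 and 157. Normexp gave 368 for dry C. flexuosa minus C. hirsuta, and correlations of 0.664 for dry C. amara and C. hirsuta, 0.795 for dry C. flexuosa and C. hirsuta and 0.644 for wet C. flexuosa and C. amara. The value table gave 356 for dry C. flexuosa minus C. hirsuta and 132 for wet C. flexuosa minus C. amara.

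Correlations follow in the order of the differences. With scan date as a block they were 0.640, 0.683 and 0.814 in dry and 0.491, 0.518 and 0.620 in wet. With no filter on dim probes these were 0.479, 0.505 and 0.712 in dry and 0.416, 0.449 and 0.509 in wet, as dim probes entered. With the stricter filter they were 0.676, 0.745 and 0.839 in dry, and 0.620 and 0.723 in wet for C. flexuosa with C. amara and with C. hirsuta.

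Leaving out each array in turn gave 2945 to 4588, 2761 to 4646 and 2760 to 3536 genes in dry, 415 to 3457, 1339 to 4970 and 734 to 861 in wet, and 2524 to 3304, 2350 to 2709 and 2294 to 2510 in dry against wet. The dry differences ranged from 680 to 1628, 390 to 974 and 158 to 384, and the wet differences from 212 to 1335, 21 to 454 and 56 to 621. Without the first-date control of a species only its second-date controls remained, so such fits compare partly across dates.

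Signal over background limits the comparison to the 44.9 to 63.9% of probes well above it on an array. Other probes of called genes had the same sign as the one used in 88.0, 87.4 and 89.8% of cases in dry and in 85.4, 80.9 and 90.4% in wet. A change in a gene whose probes bind Cardamine RNA weakly was not detectable here.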

Other observations

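All values here were chosen after the results were seen. Of the clock genes, 4 were called down in all 6 comparisons with control, while the clock list passed only in wet C. flexuosa, a call lost with an estimated correlation (adjusted p = 0.224). The morning genes CCA1 (AT2G46830) and LHY (AT1G01060), which encode the MYB factors at the core of the clock, are among these 4. CCA1 fell by 2.48, 1.90 and 2.17 in dry C. amara, C. hirsuta and C. flexuosa and by 2.99, 2.79 and 2.73 in wet, each ± 0.34, and within the first and the second scan date its values lay between -1.68 and -3.05. LHY fell by 1.44, 2.34 and 2.29 in dry and by 2.08, 2.46 and 2.3 in wet, each ± 0.37. LNK2 (AT3G54500), a coactivator of clock genes, and PRR9 (AT2G46790), a morning repressor, are the others, with falls of LNK2 by 2.29 to 2.85 ± 0.35 and PRR9 by 1.95 to 3.66 ± 0.48. The calls of CCA1 in wet C. amara and LNK2 in dry C. flexuosa were lost with the mean of all probes of a gene.

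LUX (AT3G46640), a member of the evening complex, rose by 1.73, 2.84 and 2.27 ± 0.34 in dry C. amara, C. hirsuta and C. flexuosa, and TOC1 (AT5G61380), an evening repressor, by 1.15, 1.33 and 1.34 ± 0.35. GI (AT1G22770) and ELF4 (AT2G40080), other clock genes, were not called in any dry comparison, and PRR5 (AT5G24470) fell by 1.49 in dry C. amara (adjusted p = 0.0013) and was not called in dry C. hirsuta or C. flexuosa. In wet seedlings LUX rose by 1.92 and 1.57 in C. hirsuta and C. flexuosa and was 1.07 in C. amara (adjusted p = 0.0547), while TOC1 was 1.05, 0.91 and 0.85 (adjusted p = 0.074, 0.0683 and 0.187), values that passed with scan date as a block. Controls were taken at 0 h and treated plants at 2 h in each comparison, so time of day and treatment cannot be told apart for these genes with the arrays at hand. The reference gene ACT2 (AT3G18780) had changes from -0.17 to 0.37 in the 6 comparisons, with SE of 0.30.

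Dry and wet shared called genes beyond these. In C. amara 130 genes rose and 235 fell in both treatments, against 37.4 and 61.5 if calls were independent, in C. hirsuta 302 and 702 against 95.4 and 170, and in C. flexuosa 217 and 197 against 64.8 and 45.1. Genes that rose in dry and fell in wet numbered 86, 150 and 90, against 70.5, 148 and 50.2. The reverse numbered 24, 57 and 55, against 32.6, 110 and 58.2. Dry and wet changes across genes correlated at 0.289, 0.398 and 0.400, and 0.266, 0.348 and 0.343 with scan date as a block. Arrays simulated without change or date effect gave 0.501, 0.499 and 0.502 through shared controls. Covariances were 0.136, 0.134 and 0.143 against 0.313, 0.497 and 0.399 in the data. Shared controls and scan date can add to shared calls, but how many was not computed. The 3 controls cannot be split with at least 2 on either side.

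In wet seedlings the nearness of C. flexuosa to C. hirsuta was 52.8% of 343 genes and 47.8% in the first-scan arrays, on either side of 50%, with 40.8% of 103 where the probe was brighter in C. amara and 68.3% of 120 where it was brighter in C. hirsuta.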
